A study of Mus musculus with 2 samples.

How the data were processed

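Liver RNA was measured on Affymetrix GeneChip expression arrays, on which several short probes per transcript are summarised as a probe set. Per the labels, livers were taken on postnatal day 30 from untreated mice on a C57BL/6 background, wild type (Yap+/+) or carrying 1 disrupted copy of Yap1 (Yap+/-). Livers of 5 mice per genotype were pooled before RNA was labelled with a biotin kit that starts from the 3-prime end of the messenger RNA, and each pool was hybridised to 1 array. The 5 mice of a pool are therefore 1 sample, and the 2 arrays carry no biological or technical replicates. The sex of the mice, the time of sacrifice and their feeding are not given in the sources used here.

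The deposited values are log2 probe set values made by the authors. Per the submitters' processing notes, RMA (robust multi-array average, which corrects background, quantile normalises and summarises probes) and Partek 6.5 were used, and no settings are given in the sources used here. The table held 45101 probe sets with log2 values from 2.49 to 15.2. Sorted and set side by side, the columns differed by at most 0.047, as after quantile normalisation, so an overall difference in RNA amount between the pools would largely be removed from the values of genes. Probe sets for added control RNAs and for ribosomal RNA, which are not genes here, are given in the closing section. Scanner files, detection calls and background signals were not used here, and precision is limited by the number of arrays.

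Probe sets were named from the platform annotation supplied for this table, dated after the arrays were run. Of the probe sets, 64 were array controls, 34945 had exactly 1 gene symbol, 932 had several and 9160 had none listed there. Of those with 1 symbol, 34741 had a gene identifier found in a current mouse RefSeq gene table, which changed 0 symbols. A gene was represented by the probe set with the highest mean over both arrays, which gave 18193 genes. Genes with a mean log2 value of at least 6 over both arrays, 9299 in number, were called measured and entered all counts and gene list medians, except where a value is said to be without the filter. A probe set of a multigene family, such as the Cyp2c, Cyp4a, Mup or Hspa1 genes, can bind transcripts of close relatives, and its value is uncertain to that extent.

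The comparison was the log2 value of Yap+/- minus that of Yap+/+. With 1 pool per genotype there is no test, no p-value and no error of a difference between genotypes. Genes were counted by size, at a threshold of 2-fold. For scale, the robust SD of the difference over measured genes was 0.15, and the 2 brightest probe sets of the same gene disagreed about this difference with a robust SD of 0.17 over 3406 genes. These figures cover noise within this pair of arrays and not the spread between mice or pools.

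A total of 41 gene lists was fixed before the data were examined. They were matched by current or older symbol. The number of measured members at least 2-fold higher, at least 2-fold lower and between was counted. The median difference of each list with at least 3 measured members was placed among those of 10000 random lists of the same size, drawn with replacement within 20 bins of mean expression. A list is said to stand out where its median lies within the outermost 2.5% of random lists on either side. This percentile describes these arrays. It is not a test of genotype, because genes of one pathway vary together between any 2 pools, and random lists do not. By the rule fixed beforehand, the genes named are Yap1 and Xist, up to 15 of the largest differences of at least 2-fold in each direction, up to 2 members per direction of each list (up to 4 on the side towards which a list stands out), and 10 genes chosen in advance for YAP activity, proliferation, bile ducts and hepatocytes.

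The counting and the percentiles were tested on simulated data over 9299 genes, with independent normal noise of the local robust SD of these arrays. Of 50 genes raised 2.83-fold and 50 lowered as much, 100% were counted in each direction. Of the genes changed 1.5-fold, 0% were counted, as were 0 of 9099 unchanged genes. These counts follow largely from noise set small beside the threshold. The measured differences had a wider spread, with an SD of 0.22 against a robust SD of 0.15, so the simulation gives no rate of false counts. Of 100 lists of 15 unchanged genes, 3 stood out by this rule, and of 100 lists shifted by 0.2, 99 did. Alternatives were no filter or a minimum of 7, the mean of all probe sets of a gene, only probe sets without a suffix for shared targets, median centring, removal of a lowess trend over intensity, quantile normalisation, 64 added on the linear scale, thresholds of 1.5-fold, 3-fold or 4 local robust SDs, and each list without its largest member. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.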

Results

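The livers of Yap+/- mice were compared with those of Yap+/+ mice on postnatal day 30. YAP, the product of Yap1, is the transcriptional co-activator at the end of the Hippo pathway and acts in liver growth and bile duct formation. Each genotype was represented by 1 pool of 5 livers on 1 array, so every value below is a single measurement without a replicate, and no difference between genotypes was tested. The arrays agreed closely, with Pearson's r = 0.996 across 45101 probe sets, where probe sets are not independent replicates. Of 9299 measured genes, 98.0% differed by less than 0.5 on the log2 scale. In the Yap+/- sample, control transcripts had a larger excess of 3-prime over 5-prime signal, by 0.20 for beta-actin, 0.22 for Gapdh and 0.21 for pyruvate carboxylase on the log2 scale, a mark of RNA or labelling quality that runs alongside every comparison below.

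Yap1 itself was slightly lower in Yap+/- liver. Its brighter probe set read 9.40 in Yap+/+ and 9.24 in Yap+/-, which is 1.11-fold lower, and its second probe set, at 6.01 and 5.77, gave a log2 difference of -0.24. The difference of the brighter probe set, -0.15, was within the disagreement of 0.17 (robust SD) between probe sets of the same gene. Whether either probe set lies in the deleted part of Yap1 is not given in the sources used here, so these values check the genotype labels only weakly. The 17 measured Hippo pathway components all lay within 2-fold, with a median log2 difference of 0.035 at the 78.9 percentile of random lists. The largest positive differences were Lats2, a kinase that inhibits YAP, at 1.20-fold higher, and Sav1, its scaffold partner, also at 1.20-fold higher.

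Among genes that YAP and its TEAD partners are known to activate, the matricellular genes Ccn1 and Ccn2 were lower in Yap+/-. Ccn1 was 1.61-fold lower, from 7.72 to 7.03, and Ccn2 was 1.37-fold lower, from 7.95 to 7.50. Ccdc80 was 1.23-fold higher, and Ankrd1 read 3.49 and 3.68, under the level taken as measured. As a list the 15 measured targets did not stand out, since 0 differed by 2-fold, 9 were lower and 6 higher, and the median of -0.060 lay at the 14.5 percentile of random lists. The sign of this median depended on the filter, with 0.037 at a minimum mean of 7 and 0.00 without a filter.

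The largest differences between the pools were in a few genes that were well expressed in Yap+/+ liver and much lower in Yap+/-. At the 2-fold threshold, 21 genes were lower and 9 were higher in Yap+/-. Dmbt1, a secreted mucosal scavenger receptor, read 11.2 in Yap+/+ and 4.31 in Yap+/-, a nominal 119-fold difference whose lower value lies under the median of all probe sets, 4.93, and is not shown to be above background, so the fold is not exact. Cyp2c39, a cytochrome P450 that hydroxylates retinoic acid, was 29.8-fold lower, from 11.6 to 6.67. Ctse, an aspartic protease of mucosal epithelia, was 11.3-fold lower on its bright probe set, whereas its other probe set, with a mean under the minimum, read 5.52 in Yap+/+ and 5.88 in Yap+/-. Cyp26a1, the principal retinoic acid hydroxylase, was 8.55-fold lower. Abhd1 was 7.49-fold lower and Cox6b2, a testis-type subunit of cytochrome oxidase, was 7.25-fold lower. The Yap+/- values of Cyp26a1, Abhd1 and Cox6b2, at 5.48, 5.73 and 5.06, are not shown to be above background, so these folds are not exact either. Also lower were the growth arrest gene Gadd45g (4.56-fold), G6pc, the last enzyme of glucose release (3.73-fold), the surface glycoprotein Cd24a (3.45-fold), the nuclear receptor Nr4a1 (3.29-fold), the mucin Muc1 (3.19-fold) and Pik3ap1 (2.99-fold). Cyp4a12a, a male-predominant fatty acid hydroxylase, was 2.95-fold lower, the ubiquitin ligase Lnx1 was 2.54-fold lower and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 2.39-fold lower. The same limit holds for Muc1, Cyp4a12a and Lnx1, whose Yap+/- values were 5.51, 5.66 and 5.86.

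The 9 genes at least 2-fold higher in Yap+/- differed less. Lpin1, a phosphatidate phosphatase of lipid synthesis, was highest at 2.76-fold, from 10.4 to 11.9. S100a9, a neutrophil protein, was 2.70-fold higher, Angptl8, a feeding-responsive inhibitor of lipoprotein lipase, 2.69-fold, and Nlrp12 2.68-fold. The Yap+/+ value of S100a9, 5.58, is not shown to be above background, so its fold is not exact. Hes1, a transcription factor downstream of Notch, was 2.45-fold higher. Serpina7, which encodes thyroxine-binding globulin, was 2.37-fold higher, Asns, asparagine synthetase, 2.11-fold, the heat shock gene Hspa1b 2.06-fold and the transcription factor Zbtb16 2.04-fold. Only 5 of these 30 genes had another measured probe set, and in all 5 it differed in the same direction. At a 3-fold threshold 0 genes were higher and 11 lower, whereas at a 1.5-fold threshold more genes were higher than lower.

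**Figure D1:**
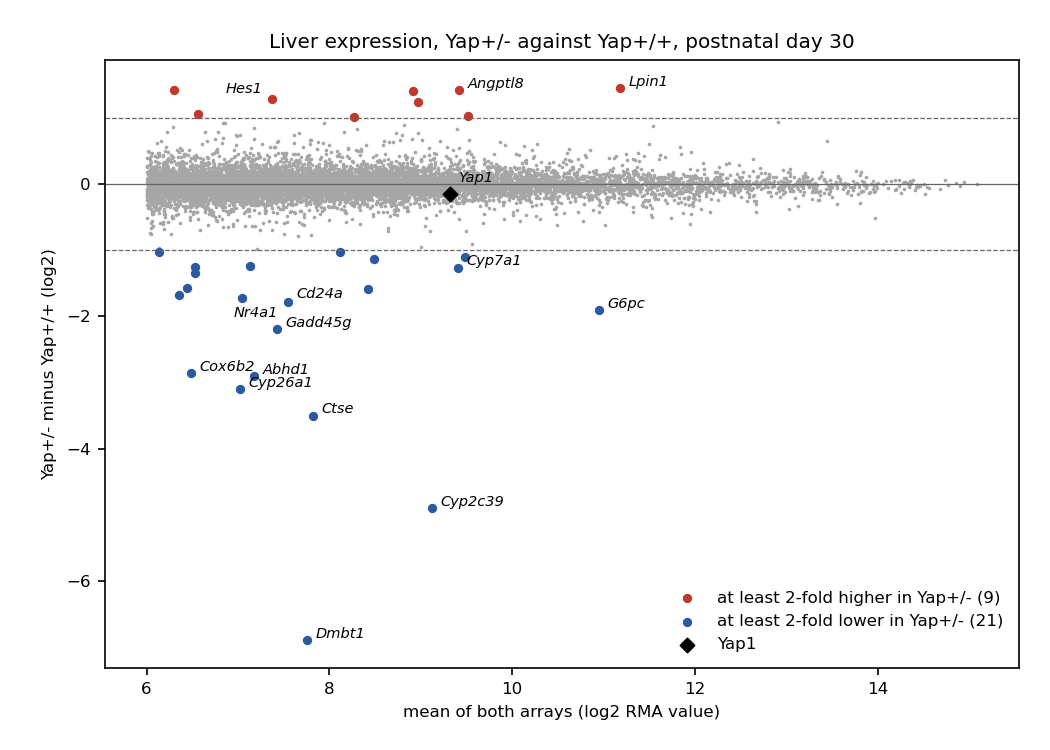
Difference between the pools (Yap+/- minus Yap+/+, log2) against the mean of both arrays (log2 RMA value) for the 9299 measured genes. Each point is 1 gene; red points are the 9 genes at least 2-fold higher in Yap+/-, blue points the 21 at least 2-fold lower, the black diamond is Yap1, and dashed lines mark 2-fold.

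**Figure D2:**
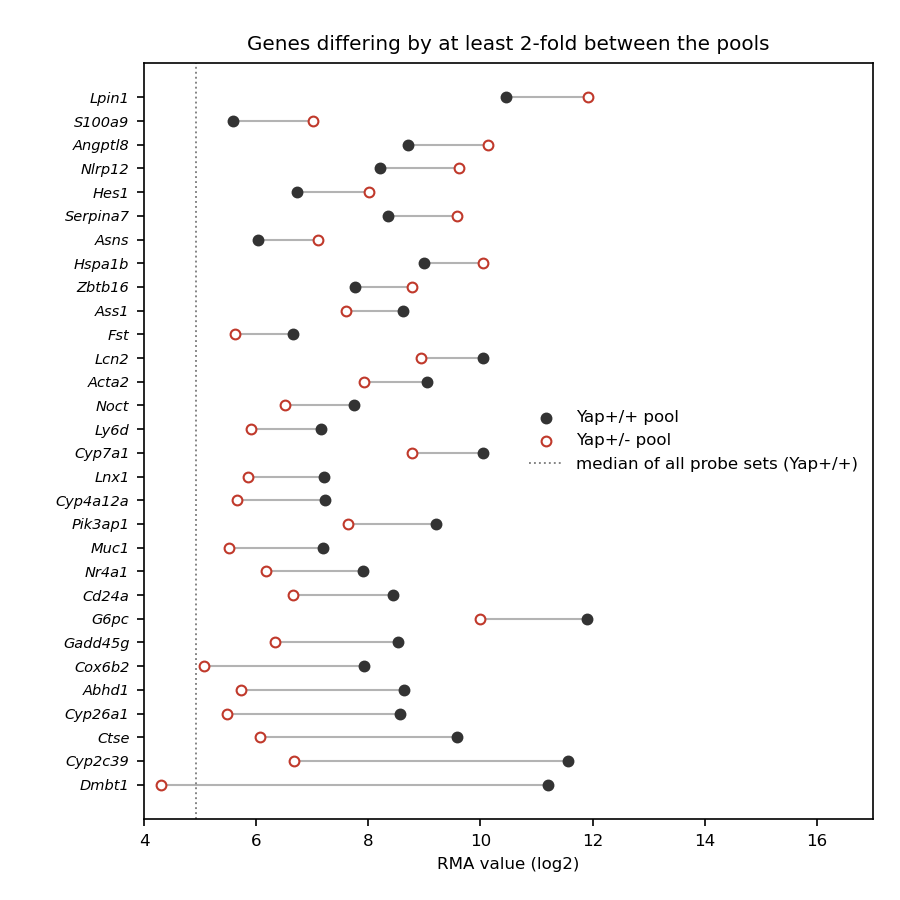
Levels (log2 RMA value) of the 30 genes that differed by at least 2-fold, with filled points for the Yap+/+ pool and open points for the Yap+/- pool. The dotted line marks the median of all probe sets on the Yap+/+ array, 4.93, and among these genes only Dmbt1 lies below it in Yap+/-.

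The study addressed postnatal liver growth and differentiation, and the proliferation genes split by phase. All 14 measured genes of mitosis and G2/M were higher in Yap+/-, none by 2-fold, with a median log2 difference of 0.18 at the 99.95 percentile of random lists. The survivin gene Birc5 was 1.36-fold higher, the mitotic kinesin Kif20a 1.33-fold, the ubiquitin-conjugating enzyme Ube2c 1.32-fold and Mki67, the Ki-67 antigen, 1.24-fold. Genes of DNA replication and G1/S went the other way, with 12 of 17 lower, none by 2-fold, and a median of -0.13 at the 0.20 percentile. The replicative helicase subunits Mcm4, Mcm6 and Mcm7 were 1.33-fold, 1.17-fold and 1.15-fold lower, and the licensing factor Cdt1 was 1.19-fold lower, whereas Ccnd1, cyclin D1, was 1.15-fold higher. Growth arrest and p53 target genes had 1 member 2-fold lower, Gadd45g, and a median of -0.045 at the 15.7 percentile, with Cdkn1a, the p21 inhibitor, 1.47-fold higher. Macrophage markers, described below, were higher in the same pool as the mitotic genes.

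Bile duct markers had a lower median in Yap+/-. Of the 9 measured biliary epithelial markers, 6 were lower, 1 of them (Muc1) by 2-fold, and the median of -0.16 lay at the 0.67 percentile. Onecut1, a transcription factor of biliary differentiation, was 1.52-fold lower, Onecut2 1.18-fold lower and Prom1 1.16-fold lower, while Jag1 was 1.14-fold higher. Krt19, the classical duct keratin, read 6.73 in Yap+/+ and 4.83 in Yap+/-, nominally 3.74-fold lower, with a mean under the minimum of 6 and the lower value also under the median of all probe sets. Sox9, a transcription factor of duct precursors, was also under that minimum at 5.56 and 5.81. Of the Notch pathway genes, 1 of 7 measured, Hes1, was 2-fold higher, and their median was 0.061 at the 79.5 percentile. Smooth muscle genes were lower in the same pool as the duct markers. Acta2, smooth muscle actin, was 2.19-fold lower on its only bright probe set, whereas the next brightest, near background, differed by 0.034 on the log2 scale, and Tagln was 1.69-fold lower.

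Hepatocyte identity genes did not stand out as a group. The median over 22 measured members was -0.0002, at the 55.6 percentile, and 11 members were lower and 10 higher. Alb, albumin, read 15.1 on both arrays, close to the highest value of the table, 15.2, where a difference would hardly show. Ass1, an enzyme of the urea cycle, was 2.03-fold lower on the only probe set with its symbol, which read 8.63 and 7.61. Other urea cycle genes of the list read far higher and differed little, with Cps1 at 14.3 and Otc at 13.3 on both arrays. Whether the Ass1 probe set reads the main transcript is therefore uncertain. The xenobiotic receptor Nr1i3 was 1.34-fold lower and its relative Nr1i2 was 1.37-fold higher, as was the transcription factor Foxa3 at 1.39-fold. Fetal liver genes had a median of 0.012 over 10 measured members, at the 61.6 percentile, and a mean of -0.14, with Cd24a the only member past 2-fold, and Afp, alpha-fetoprotein, under the minimum at 5.75 and 5.66. The 26 measured drug-metabolising cytochrome P450 genes had a median of -0.0425, at the 5.4 percentile, and 19 were lower. Besides Cyp2c39, the largest among them were Cyp2c38 at 1.88-fold lower and Cyp2c23 at 1.38-fold higher.

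Several metabolic lists had lower medians in Yap+/-, by small amounts. NRF2 target genes had 13 of 14 members lower and a median of -0.23, below all 10000 random lists, with Ugdh 1.47-fold, the epoxide hydrolase Ephx1 1.42-fold, the exporter Abcc3 1.39-fold and the malic enzyme Me1 1.37-fold lower. The exception was Hmox1, haem oxygenase, at 1.47-fold higher. Cholesterol synthesis genes had 18 of 20 lower and a median of -0.18, also below all random lists, led by Fdps and Mvd, both 1.33-fold lower, Msmo1 at 1.27-fold and Nsdhl at 1.25-fold. Bile acid synthesis and transport genes had 15 of 24 lower and a median of -0.14, below all random lists. Cyp7a1 was the only member past 2-fold, Cyp8b1, which sets the cholic acid share, was 1.52-fold lower, and Nr0b2, the repressor SHP that acts on both, was 1.79-fold higher. Conjugating enzymes had 23 of 28 lower and a median of -0.10, below all random lists, with Sult3a1 at 1.48-fold lower and the oestrogen sulphotransferase Sult1e1 at 1.87-fold higher. Lipogenesis genes (median -0.0555), PPAR-alpha and fatty acid oxidation genes (0.030) and gluconeogenesis and fasting genes (0.022) did not stand out, at the 6.7, 88.8 and 78.4 percentiles, although Thrsp was 1.52-fold lower, the fatty acid transporter Cd36 1.63-fold lower and Foxo1 1.57-fold higher. Without the filter the lipogenesis list lay at the 1.75 percentile. Pericentral zone genes had 10 of 12 lower and a median of -0.15, at the 0.07 percentile, led by the Wnt receptor component Lgr5 at 1.55-fold and the transcription factor Tbx3 at 1.34-fold lower. The periportal list had a median of -0.067, at the 6.6 percentile, and the difference between the zones was not tested.

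Macrophage and sinusoidal endothelial markers had higher medians in Yap+/- liver. Of 15 Kupffer cell and macrophage markers, 14 were higher and 0 lower, with a median of 0.26 above all random lists and examples in the scavenger receptor Marco at 1.54-fold, Cd68 at 1.39-fold, Cd5l at 1.35-fold and Adgre1 at 1.34-fold. Sinusoidal endothelial markers had 12 of 15 higher and a median of 0.15, at the 99.8 percentile, with Clec4g at 1.22-fold and Fcgr2b at 1.28-fold, although 1 of the 3 other measured probe sets of Fcgr2b was lower, by a log2 difference of -0.14. Only 4 lymphocyte markers were measured, and they were higher with a median of 0.37, led by the chemokine Ccl5 at 1.54-fold. Without the filter this list had 17 members, a median of 0.085 and no longer stood out. Interferon-stimulated genes had a median of 0.095, at the 98.9 percentile, with Gbp3 at 1.35-fold and Cxcl10 at 1.34-fold. Stellate cell and matrix genes (median 0.042, mean -0.051) and erythroid genes (median -0.011) did not stand out, at the 88.0 and 49.2 percentiles. Of the neutrophil, exocrine pancreas and adipose lists, 2 members each were measured, too few for a percentile, and of these S100a9 alone was past 2-fold. Among members under the minimum, chosen here after their values were seen, the neutrophil gene S100a8 read 4.36 in Yap+/+ and 5.95 in Yap+/-, and the pancreas genes Reg1 and Ctrb1 read 5.82 and 6.41 in Yap+/+ and 4.05 and 5.13 in Yap+/-, levels at which a fold is not exact.

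Stress and acute-phase lists also had higher medians in Yap+/-. Unfolded protein response genes had 14 of 15 higher and a median of 0.19, above all random lists, and besides Asns these were led by Ddit3, the factor CHOP, at 1.72-fold, Herpud1 at 1.48-fold and Trib3 at 1.22-fold. Acute-phase genes had 20 of 24 higher and a median of 0.080, at the 99.9 percentile, with the metallothioneins Mt2 and Mt1 at 1.93-fold and 1.58-fold, Socs3 at 1.53-fold and Saa3 at 1.44-fold, while Lcn2, lipocalin-2, was 2.15-fold lower. Heat shock genes had 6 of 9 higher and a median of 0.14, at the 99.7 percentile, with Hsph1 1.69-fold higher but Hspb1 1.46-fold and Bag3 1.11-fold lower. Their median was -0.054 when only probe sets without a suffix for shared targets were used. Immediate early genes had a median of 0.064, at the 88.6 percentile, and a mean of -0.054, and they went both ways, with Junb 1.62-fold higher and Dusp1 1.63-fold lower.

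Sex-linked transcripts did not separate the pools. Xist, the RNA of the inactive X chromosome, read 12.8 in Yap+/+ and 12.7 in Yap+/-, on its brightest probe set, while another measured probe set differed by 0.020 in the other direction, and 9 probe sets of 3 Y-linked genes lay between 2.65 and 3.59 on both arrays. These Y-linked values lay near the lowest value of the table, 2.49, so both pools read as female, although the labels do not give the sex. Male-biased liver genes were nevertheless lower, with 7 of 11 lower and a median of -0.21 below all random lists, led by Cyp4a12a, the transporter Slco1a1 (1.39-fold), the fatty acid elongase Elovl3 (1.36-fold) and Cyp2d9 (1.34-fold), although 4 were higher, among them C6 at 1.27-fold and Mup3 at 1.15-fold. Female-biased genes had 8 of 12 higher and a median of 0.23 above all random lists, but a mean of 0.071. They include Cyp2b13 at 1.33-fold, Slc22a26 at 1.30-fold, Cyp17a1 at 1.28-fold and Cyp2b9 at 1.25-fold, although Sult3a1 was 1.48-fold and Atp6v0d2 1.46-fold lower. Growth hormone and IGF axis genes had a median of 0.065, at the 95.7 percentile, with the leptin receptor Lepr 1.83-fold higher. Circadian clock genes had 9 of 14 higher, a median of 0.12, at the 99.6 percentile, and a mean of 0.075. Usp2 was 1.60-fold, Per1 1.45-fold, Dbp 1.38-fold and Bhlhe40 1.25-fold higher, while Noct was 2.36-fold and Arntl 1.21-fold lower. Without the filter the clock list lay at the 96.2 percentile and the heat shock list at 94.6.

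In all, 18 of 37 lists with a percentile stood out, 10 above and 8 below, where independent genes would give 1.85. Members of a list vary together between any pair of pools, so an excess can arise between pools of the same genotype, and how large it would be was not measurable with 1 pool each. Cytosolic ribosomal protein genes (median 0.020, percentile 93.2), respiratory chain genes (median 0.017, mean -0.031, percentile 95.2), complement and coagulation genes (median 0.035, percentile 92.8) and the 3 measured major urinary protein genes (median 0.00, mean -0.11, percentile 51.0) did not stand out.

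**Figure D3:**
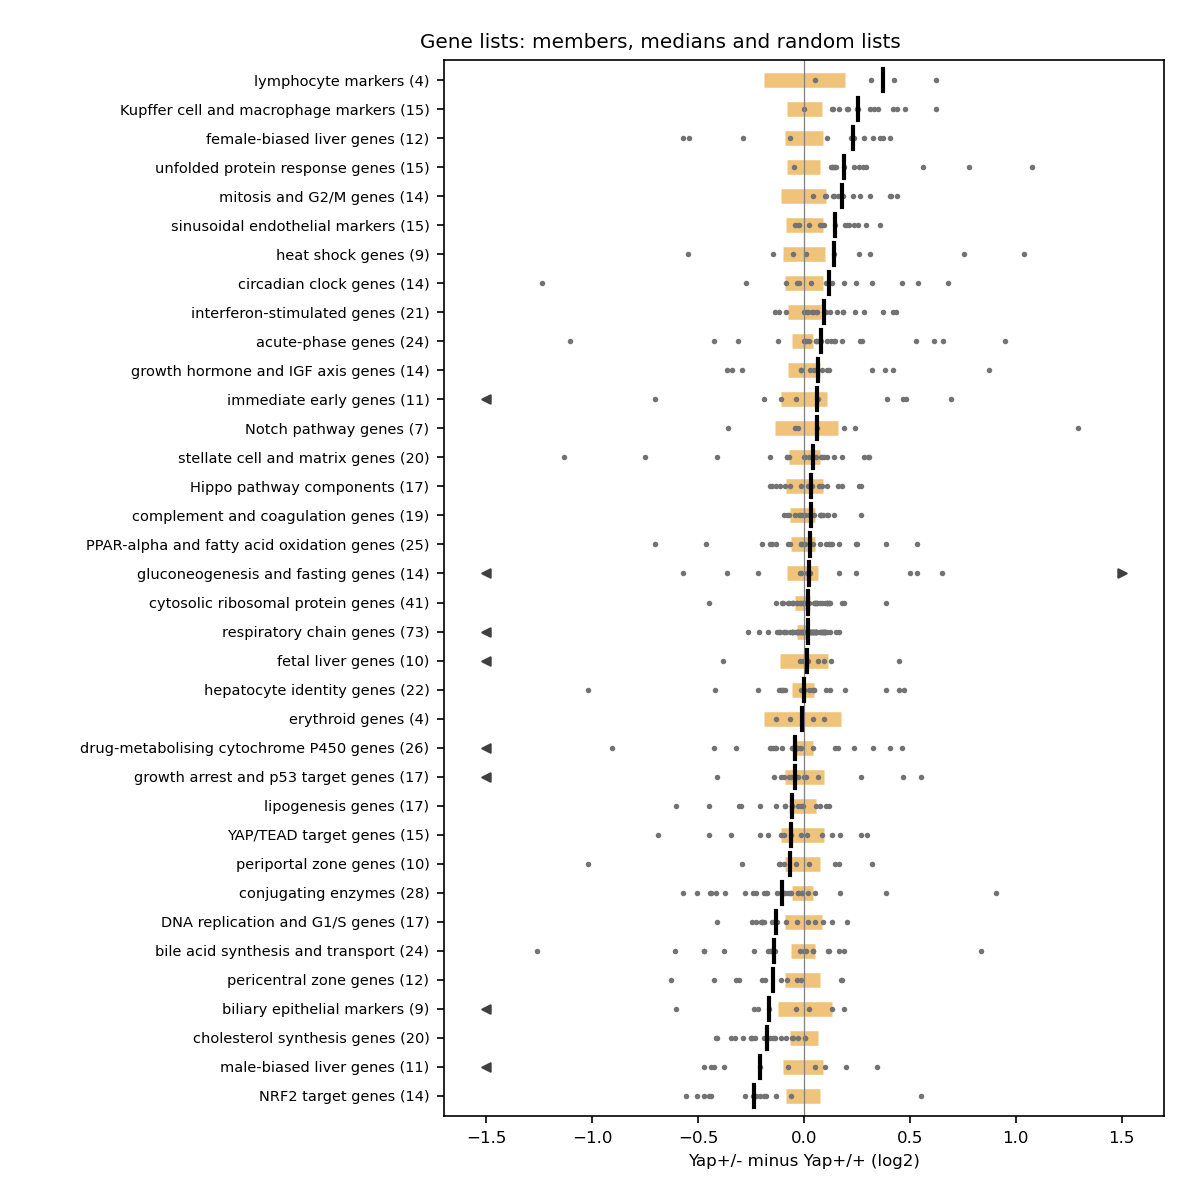
Log2 difference (Yap+/- minus Yap+/+) of the measured members of each gene list with at least 4 measured members (number in parentheses). Grey points are genes, and arrowheads at a fixed place near each edge stand for genes with larger differences, whose values they do not mark. Black bars are list medians, and orange bands hold the medians of 10000 random lists matched on expression, without the outermost 2.5% on either side. NRF2 target genes have the lowest median, -0.23, and lymphocyte markers the highest, 0.37.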

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

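Among measured probe sets that carry no gene symbol or several, 12 were at least 2-fold higher in Yap+/- than in the Yap+/+ control and 4 were at least 2-fold lower, out of 1704. They stand out because no gene-level comparison uses them. The most different had no symbol and read 9.72 in Yap+/+ and 5.24 in Yap+/-, nominally 22.3-fold lower, a fold that is not exact at the lower level. The one furthest in the other direction was 3.42-fold higher in Yap+/-.

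Array control probe sets, which the gene comparison leaves out, also differed between the arrays. The 24 probe sets for poly-A RNAs added to the sample before labelling were all higher on the Yap+/- array, with a median log2 difference of 0.69 and a range of 0.28 to 1.12. The 18 probe sets for RNAs added at hybridisation were all higher too, with a median of 0.31, and the 3 probe sets for 18S ribosomal RNA were lower, with a median of -0.91.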

How the results depend on the processing

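Of the alternatives in this part, only the removal of biliary, mucosal epithelium and smooth muscle genes was chosen after seeing the data. With 1 array per genotype no replicate could be left out and no other split of the samples exists. No paired analysis was possible because each genotype has 1 sample, so the alternatives say nothing about the spread between mice. The number of genes at least 2-fold higher in Yap+/-, 9, became 65 at 1.5-fold, 0 at 3-fold, 66 at 4 local robust SDs and 4 with 64 added on the linear scale. The number of genes at least 2-fold lower in Yap+/-, 21, became 60, 11, 53 and 13 under the same changes, and 37 without the filter. More genes were thus lower than higher at 2-fold and 3-fold, and fewer at 1.5-fold and at 4 local SDs. Without biliary, mucosal epithelium and smooth muscle genes, 9 were higher and 14 lower. The median log2 difference of DNA replication and G1/S genes moved to -0.19 with the mean of all probe sets, and the median log2 difference of mitosis and G2/M genes to 0.27 at a minimum mean of 7. The median log2 difference of YAP/TEAD target genes became 0.037 at that minimum and 0.00 without a filter. With only probe sets without an _s, _x or _a suffix, the log2 difference of Acta2 went from -1.13 to 0.034, because its bright probe set is an _s set and the next is near background, and the median log2 difference of heat shock genes went from 0.14 to -0.054, whose cause was not tested. Among the other values of named genes, 1390 moved by less than the disagreement between probe sets of a gene and 80 by more. Among the other list medians, 233 moved by less than the SD of random lists and 32 by more. Signal over background limits genes near the floor, where folds are understated.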

Other observations

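The tests and added lists in this part were chosen after the results they bear on had been seen, and for the retinoic acid response genes only the bound was written before the value tested was seen. Antigen presentation genes of MHC class II were higher in Yap+/- together, with a median log2 difference of 0.62 over 5 measured members, above all 10000 random lists. H2-Ab1 was 1.78-fold, H2-Aa 1.56-fold, Cd74, the invariant chain, 1.54-fold and H2-Eb1 1.51-fold higher. In the same pool Kupffer cell and macrophage markers had 14 of 15 members higher and a median of 0.26, and Ptprc, the leukocyte antigen CD45, was 1.25-fold higher. Target genes of ATF4, the transcription factor of the amino acid response, had 10 of 14 measured members higher and a median of 0.15, at the 99.95 percentile, but they include Asns, Ddit3 and Trib3, already seen to be higher. Without these 3 the median was 0.11, at the 98.3 percentile, and without the glutathione-degrading enzyme Chac1 as well, 1.53-fold higher, it was 0.076, at the 94.6 percentile, and did not stand out. Asns, Ddit3 and Chac1 had the largest differences among the measured ATF4 targets, so the fall of the median on their removal was partly built in. The MHC class II and ATF4 lists were both assembled after the largest differences had been seen, so their percentiles partly restate what prompted them.

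The genes with the largest negative differences include several of duct or mucosal epithelium, and smooth muscle genes were lower with them. Ctse, Muc1, Ly6d and Cd24a were lower by 2.38-fold to 11.3-fold, Dmbt1 and Krt19 were lower to values under the median of all probe sets, where a fold is not exact, and Myl9, Tpm2, Acta2 and Tagln by 1.69-fold to 2.19-fold. The Yap+/- values of Muc1 and Ly6d, 5.51 and 5.91, are not shown to be above background either. More gallbladder or large duct tissue in the Yap+/+ pool stays open for both parts. For the smooth muscle part, 12 smooth muscle genes outside those already named had a median of -0.29 without the filter. The 6 of them that were measured had -0.23, at the 0.31 percentile. Smooth muscle genes were thus lower beyond those named, but their source is not shown, since vessels hold these genes too. For the epithelium part, 11 further duct genes had 10 lower and a median of -0.14 at the 2.1 percentile without the filter. Their differences were much smaller than those of the duct genes named above. They do not decide, because 9 of them were under the minimum mean of 6, near the floor. Greater loss of 5-prime signal in the Yap+/- sample is not settled for all of these genes. The median of all 19 measured genes of both kinds was -0.75, and 13 of them lay below the largest difference of a 5-prime control probe set, -0.31. A loss no larger than in the controls would not reach the values of these 13. The others lay above -0.31, and for them such a loss stays open. The lower Yap1 gene dose cannot be told apart from these, because genotype and pool coincide and the YAP/TEAD target median of -0.060 does not decide.

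The 6 genes at least 7-fold lower in Yap+/- (Dmbt1, Cyp2c39, Ctse, Cyp26a1, Abhd1 and Cox6b2) could come from strain DNA flanking the targeted Yap1 locus or from a fault of single probe sets. DNA flanking the targeted Yap1 locus, acting on genes it carries, is argued against, since 0 of the 6 genes were among the 60 measured neighbours of Yap1 and 0 lay on its chromosome. Among those neighbours Angptl8, at 2.69-fold higher, was the only gene past 2-fold. A fault of single probe sets cannot be told apart from a difference in the transcript, because 0 of the 6 had another measured probe set, and the other probe set of Ctse, which was under the minimum mean and 0.36 higher in Yap+/-, does not show the difference of the bright one. The Yap1 genotype, and a single unusual mouse within a pool, stay open and were not tested.

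Lpin1, Angptl8 and Nr0b2 were higher and G6pc, Cyp7a1 and Noct lower in Yap+/-, genes known to vary with the clock, feeding or stress hormones. Angptl8 is also a neighbour of Yap1, and DNA flanking the targeted locus was not tested as an explanation for it. For a different time of day at sacrifice, 7 clock output genes lay 0.27 above 3 clock genes of the opposite phase, at the 98.7 percentile, but this test was narrowed after its result was seen to genes outside the fixed naming rule, and the 4 and 2 genes left gave 0.14 at the 86.4 percentile. For more glucocorticoid signalling, all 20 listed targets had a median of 0.15, above all random lists, and after the same narrowing the 10 left had -0.11, at the 0.69 percentile, with 6 lower and 4 higher, among them Sgk1 1.55-fold lower and Fkbp5 1.44-fold higher; an earlier narrowing to 8, which also left out Tat and Cebpb by mistake, had the same median at the 1.57 percentile. The first bound, on the percentile alone, would have labelled this explanation excluded. After the value of the 8 was seen, the bound was changed to ask also that a larger share of members than in either version be lower. The naming rule picks genes mostly by the size of their difference on these arrays, and the random lists were not narrowed in that way. The narrowed values of the time-of-day and glucocorticoid tests partly follow from this and exclude nothing. For a different feeding state, lipogenesis genes lay at -0.041 relative to genes higher in fasting, at the 24.2 percentile. This depended on the filter. Without it the lipogenesis median was -0.072, at the 1.75 percentile, and the fasting median was 0.076, at the 95.3 percentile. The gap between them was not placed among random lists without the filter, and the fasting list includes G6pc, named above. These explanations and the Yap1 genotype cannot be told apart here, since each test rests on few genes, on genes that go both ways or on genes already seen to differ.

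Cyp26a1 and Cyp2c39 both hydroxylate retinoic acid, and Cyp26a1 is induced by it, so lower retinoic acid signalling in Yap+/- was tested as a hypothesis on 10 other retinoic acid response genes. Without the filter their median was -0.016, at the 43.5 percentile, which did not decide. Of the 10, 5 were under the minimum mean of 6, where folds are not exact, among them Rarb, nominally 1.76-fold lower, and Cyp26b1, nominally 1.53-fold higher.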
